A study of Mus musculus with 4 samples.

How the data were processed

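Open chromatin was profiled by FAIRE-seq (formaldehyde-assisted isolation of regulatory elements followed by sequencing) in 2 samples of a C57BL/6 mouse embryonic stem (ES) cell line and 2 samples of a C57BL/6 mouse trophoblast stem (TS) cell line. In this assay chromatin is crosslinked and sheared, and DNA that is poorly covered by nucleosomes is recovered from the aqueous phase of a phenol-chloroform extraction. Per the labels' protocols, both kinds of cell were grown on feeder cells, and feeder-free cells were collected for fixation. Samples were grouped by cell line and named by the replicate number in their titles. Nothing in the labels says whether replicates came from separate cultures, so the spread between them may be technical.

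Each deposited file was the peak list of 1 sample, so peaks were called per sample and not on pooled samples. Per the submitters' processing notes, CASAVA 1.8.1 and MACS were used, with the mouse genome build mm9. The aligner and any handling of duplicate reads are not given in the sources used here. Per the file headers, MACS was run with an average fragment length of 200 bp, an effective genome size of 1870000000 bp, a p-value limit of 1e-05, enrichment limits of 5 and 50, a dynamic background (lambda) and a padding of 5000. No untreated or input sample was analysed here.

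The deposited P score behaved as the −log10 p-value of each peak: its lowest values lay just above 5, and its highest, 323.306, is the smallest p-value that double precision can hold. The deposited fold change is a ratio of the read pileup at the summit to the local background. The deposited Q score is the authors' own correction of the P score. It exceeded the P score for 0.0579% of peaks in ES replicate 1 and for 44.1% in TS replicate 2, as an ordinary q-value cannot, and it was not used. A peak's P score and fold are the authors' values, and as such they were used to describe, rank or filter peaks within the same list. Pileup, local background and tag number were also derived from them, and of these the tag numbers and the background ratios, each relative to its own list, were set side by side between lists.

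Total read counts are not given in the sources used here, but the P score and fold of a peak together fixed its pileup. The fold was taken as (pileup + 1) / (background + 1), and the P score as −log10 of the Poisson probability of a higher pileup. Whole-number pileups from 3 to 1499 were searched for the one that gave the P score within 0.001. A solution was found for all peaks of ES replicate 1 and TS replicate 1, for 99.9% of peaks in ES replicate 2 (10 peaks had none) and for nearly all in TS replicate 2 (5 peaks had none). The lowest background in each list was taken as the genome-wide background, which MACS sets to the number of tags times the fragment length over the genome size. This gave 41.9 and 42.1 M tags (mega-tags) for ES replicates 1 and 2, and 54.3 and 39.8 M tags for TS replicates 1 and 2. These depths are reconstructed and cover only the tags that the caller kept. The local background of a chromosome is given as the 75th percentile over its peaks, divided by the median of that value over the 19 autosomes. The 75th percentile was picked after the median, the 75th and the 90th percentile had all been looked at, and the values at the other percentiles are given where they bear on a statement. The caller's floor at the genome-wide background compresses this ratio.

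Peaks from the 4 lists that shared at least 1 bp were merged into regions. A region was called in a sample when it held a peak of that sample. ES-only regions were called in both ES samples and in no TS sample, and TS-only regions the other way round. Counts expected for independent lists were computed from the share of all merged regions that each sample called; because a region enters only when at least 1 sample called it, these counts are a rough yardstick. Peak numbers were compared by a two-sided exact permutation test of the group means over the 3 distinct splits of 4 samples into 2 and 2, which cannot give a p-value below 0.333. Chromosome X shares were compared by a two-sided Fisher's exact test, and by a Mantel-Haenszel odds ratio stratified by replicate number. The 1 Mb windows with at least 5 cell-type-only regions were each compared with the rest of the genome by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment. Regions are not independent replicates, so these p-values and the exact (Clopper-Pearson) 95% intervals of shares cover counting error only. Strength within a list was summarised as the probability that a peak in a region called in all 4 samples had a higher fold than a peak in a region of the list's own cell type only.

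The design, the alternatives, and the rule for named items were fixed before the data were examined. The rule named the 5 regions per class with the highest fold percentile in the weakest sample, and the 10 windows with the lowest p among those past an adjusted p of 0.05. Alternatives were peaks above each list's median P score, lists cut to the 12100 strongest peaks by P score, an overlap of 50% of the shorter peak, joining of peaks within 500 bp, autosomes only, windows of 500 kb and 2 Mb, and leaving out each sample. The comparisons of chromosomes 11 and 6 and of same-numbered samples were not planned and were made after those patterns had been seen. Leaving out chromosome 11, using each replicate number alone, and every alternative for the chromosome 11 share were chosen after seeing the data. The planned comparisons by promoter, by gene list and at Tead4, and their alternatives, were not made. They need gene positions in mm9, which were not used here: the gene table at hand follows another build (GRCm38). Positions are printed as in the deposited lists (mm9); whether those count the first base as 0 or 1 is not stated in the sources used here.

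Interval code, pileup recovery, the window test and the shuffling (permutation) test of clusters were tested on simulated data. Pileup and background were recovered for 100% of 3798 simulated peaks. All of 1486 planted ES-only, 13485 planted TS-only and 5943 planted shared regions were found. Each was planted in every sample of its class and apart from its neighbours, so this checks the code only. It does not measure how well real regions are recovered. With TS-only regions turned to ES-only in planted windows, the window test called 0% of 20 windows with 30% of regions turned, 42.1% of 19 with 60% turned and 100% of 19 with 90% turned. The low recovery at 30% and 60% shows that it can miss differences of those sizes. ES-only regions were a larger part of the cell-type-only regions there than in the data (5.10%), so these rates do not carry over directly. It called 0 of the other windows among 1748. The permutation test of clusters, by shuffling, gave p = 0.574 for 2964 simulated regions placed at random and p = 0.001 for 2788 placed in runs of 3. The union of the 4 real lists held 54693 regions both by this code and by bedtools 2.31.1. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.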

Results

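Accessible chromatin was mapped by FAIRE-seq in mouse ES cells, which derive from the inner cell mass of the blastocyst, and in mouse TS cells, which derive from the trophectoderm and can form the placenta. The series concerns the regulation of Tead4, a transcription factor gene needed for the trophectoderm, by elements on other chromosomes. The comparison of the 2 cell types shows which regions were called as peaks in the samples of each. Each cell type had 2 samples. The reconstructed depth was 42.0 ± 0.158 M tags (mega-tags) in ES cells and 47.0 ± 10.2 M tags in TS cells (mean ± SD, n = 2 each).

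TS cells yielded more FAIRE peaks than ES cells. The TS lists held 33817 and 34915 peaks (34366 ± 776, SD, n = 2), and the ES lists held 12100 and 16361 (14230.5 ± 3013, SD, n = 2), a ratio of 2.41. Peaks covered 9.33 ± 0.639 Mb in TS cells and 3.30 ± 1.42 Mb in ES cells (SD, n = 2 each). Both TS samples lay above both ES samples, and the difference exceeded the spread between replicates. The two-sided exact permutation test gave p = 0.333, the smallest that this test can give with 2 samples against 2. Peak number did not follow depth: TS replicate 2 had the fewest tags, 39.8 M, and the most peaks. The median peak length was 155 bp and 229 bp in ES replicates 1 and 2, and 227 bp and 244 bp in TS replicates 1 and 2. The median fold over local background was 4.38 and 5.63 in the ES lists, and 5.00 and 6.09 in the TS lists.

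The TS replicates resembled each other more than the ES replicates did. TS replicate 2 overlapped 66.8% of the peaks of TS replicate 1, and the reverse share was 64.6%. ES replicate 2 overlapped 49.98% of the peaks of ES replicate 1, and the reverse share was 36.4%. The Jaccard index (shared over covered bases) was 45.3% between the TS lists and 23.6% between the ES lists. Between cell types it was 15.7% for the pair numbered 1, 22.5% for the pair numbered 2, and 12.6% and 15.99% for the crossed pairs. By share of peaks, ES replicate 1 had more in TS replicate 1 (62.8%) and in TS replicate 2 (54.1%) than in ES replicate 2. The same held for ES replicate 2, with 44.2% in TS replicate 1 and 62.9% in TS replicate 2 against 36.4% in ES replicate 1. Both ES lists were shorter than the TS lists. Averaged over both directions, 54.4% of peaks were overlapped within a cell type and 39.5% between cell types, and this difference of 15.0 percentage points was smaller than the spread between the 2 within-type pairs (SD 15.9). It rested on single samples: it was 1.95 and 5.53 percentage points without TS replicates 1 and 2, and 26.1 and 26.3 without ES replicates 1 and 2.

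The 4 lists merged into 54693 regions. TS-only regions numbered 14436, ES-only regions 776, and 4675 regions were called in all 4 samples. Independent lists would have given 11733 TS-only, 499 ES-only and 1390 regions in all 4 samples. Of the 5947 regions called in both ES samples, 78.6% were also called in both TS samples and 87.0% in at least 1. Of the 22422 regions called in both TS samples, 20.9% were called in both ES samples. A further 25912 regions, 47.4% of the total, were called in a single sample. The imbalance between the classes depended on list length: with each list cut to its 12100 strongest peaks, TS-only regions numbered 2923 and ES-only regions 936, a ratio of 3.12 in place of 18.6. With peaks above each list's median P score and the classes made anew, TS-only regions numbered 6632 and ES-only regions 164.

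**Figure D1:**
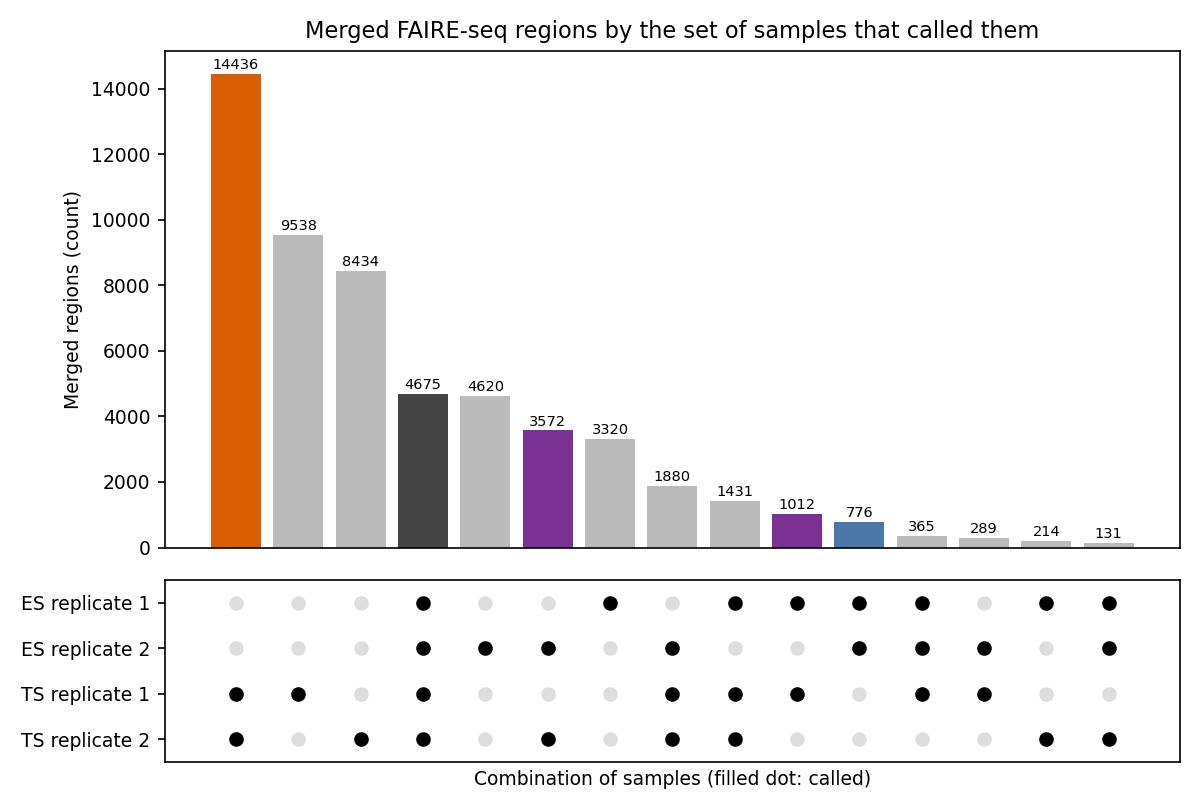
Number of merged regions (vertical axis, count) for each combination of samples that called them (filled dots below each bar): blue marks ES-only, orange TS-only, dark grey all 4 samples, purple the pairs of 1 ES and 1 TS sample with the same replicate number, and light grey the rest. The 14436 TS-only regions form the tallest bar, and 3572 regions were called only in the 2 samples numbered 2.

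Regions shared by 1 ES and 1 TS sample went largely by replicate number, a pattern noticed in the data and not among the planned comparisons. ES replicate 2 and TS replicate 2 alone shared 3572 regions, against 289 shared by ES replicate 2 and TS replicate 1 alone. ES replicate 1 and TS replicate 1 alone shared 1012 regions, against 214 shared by ES replicate 1 and TS replicate 2 alone. Same-numbered pairs thus held 4584 such regions and crossed pairs 503, a ratio of 9.11. The regions of the pair numbered 2 were strong. Their median P score was 24.5 in ES replicate 2 and 26.5 in TS replicate 2, against list medians of 17.0 and 18.9. Of these regions, 12.7% lay on chromosome X and 3.14% on chromosome 11, against 1.25% and 11.8% of TS-only regions. The shares were 12.5% and 3.46% for the pair numbered 1. They were 8.14% and 2.81% for regions called in ES replicate 2 alone, and 3.89% and 8.82% for those in TS replicate 2 alone. Within replicate number 1, 26302 regions were called in TS cells alone and 4500 in ES cells alone; within number 2 the counts were 24608 and 6066.

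Regions called in all 4 samples carried stronger peaks than those of 1 cell type only. A call in every list itself selects strong peaks, and regions called in both cell types but in fewer samples were not always stronger: in ES replicate 1, the median fold was 4.13 in those shared with both TS samples alone, against 4.22 in ES-only regions. In the TS lists the median fold was 6.70 and 8.38 in regions called in all 4 samples, against 5.10 and 5.90 in TS-only regions. In the ES lists it was 4.72 and 5.98 in regions called in all 4 samples, against 4.22 and 4.85 in ES-only regions. A peak of a region called in all 4 samples had the higher fold with a probability of 0.636, 0.734, 0.765 and 0.774 in ES replicates 1 and 2 and TS replicates 1 and 2 (mean 0.727). Regions called in all 4 samples also held longer peaks, with medians of 320 and 338 bp in the TS lists against 251 and 264 bp in TS-only regions.

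The strongest TS-only region lay on chromosome 18 at 43135434 to 43135749 (mm9). Its fold was 15.9 in TS replicate 1 and 16.5 in TS replicate 2, from pileups of 113 and 93 tags over local backgrounds of 6.15 and 4.71 tags. It was followed by a region on chromosome 14 at 53877018 to 53877577, with folds of 13.2 and 13.5, and a region on chromosome 18 at 78341580 to 78342005, with folds of 9.58 and 12.9. A region on chromosome 2 at 103502343 to 103502759 had folds of 9.51 and 12.8, and a region on chromosome 8 at 125159691 to 125160204 had folds of 9.22 and 12.6. All 5 lay above the 97.8th percentile of fold in both TS lists.

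The strongest ES-only region lay on chromosome 9 at 106014251 to 106014705, with folds of 20.8 and 17.8 in ES replicates 1 and 2 and pileups of 113 and 122 tags. A region on chromosome 7 at 137918265 to 137918518 followed, with folds of 13.9 and 9.97. The other 3 were weaker. They lay on chromosome 1 at 74871483 to 74871930 (folds of 6.33 and 7.81), on chromosome 5 at 115914795 to 115915142 (6.39 and 7.45) and on chromosome 7 at 138905940 to 138906210 (7.30 and 7.45). A region not called in the other cell type is one without a peak there, which does not show that its signal was absent.

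The strongest regions called in all 4 samples reached folds of 15.0 to 34.4. They lay on chromosome 8 at 15519780 to 15520105, chromosome X at 166649927 to 166650296, chromosome 9 at 123370927 to 123371362, chromosome 18 at 68851659 to 68851951 and chromosome 2 at 181747428 to 181748015. The region on chromosome X had the highest fold of both TS lists, 27.5 and 34.4. The local background of the region on chromosome 2 was 10.4 tags in ES replicate 2 and 9.91 tags in TS replicate 2. It was 4.67 tags in ES replicate 1 and 5.80 tags in TS replicate 1. Peaks were not screened for repeated or hard-to-map sequence, so a high fold in all 4 samples need not mark open chromatin.

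Chromosome 11 held a larger share of TS than of ES peaks, a comparison made after the chromosome counts had been seen. It held 10.5% (exact 95% interval 10.2 to 10.8) and 9.54% (9.23 to 9.85) of peaks in TS replicates 1 and 2, against 6.83% (6.39 to 7.30) and 5.56% (5.21 to 5.92) in ES replicates 1 and 2. The ratio of mean shares was 1.62 (two-sided exact permutation test, p = 0.333, the smallest possible), and it was 1.53 and 1.72 within replicate numbers 1 and 2. Of the other autosomes, chromosome 15 had the highest ratio, 1.16, and chromosome 6 the lowest, 0.731. Chromosome 11 held 1705 TS-only regions and 49 ES-only regions. The local background at chromosome 11 peaks was 1.37 and 1.42 times the autosomal median in the TS lists, and 0.999 and 1.02 times in the ES lists. The highest other autosome, chromosome 4, was at 1.05 and 1.06 in the TS lists. At the 90th percentile of background, chromosome 11 was at 1.42 and 1.43 and the highest other autosome at 1.16 and 1.13. Without chromosome 11 the ratio of peak numbers between the cell types was 2.31, and TS-only regions numbered 12731 and ES-only regions 727.

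**Figure D2:**
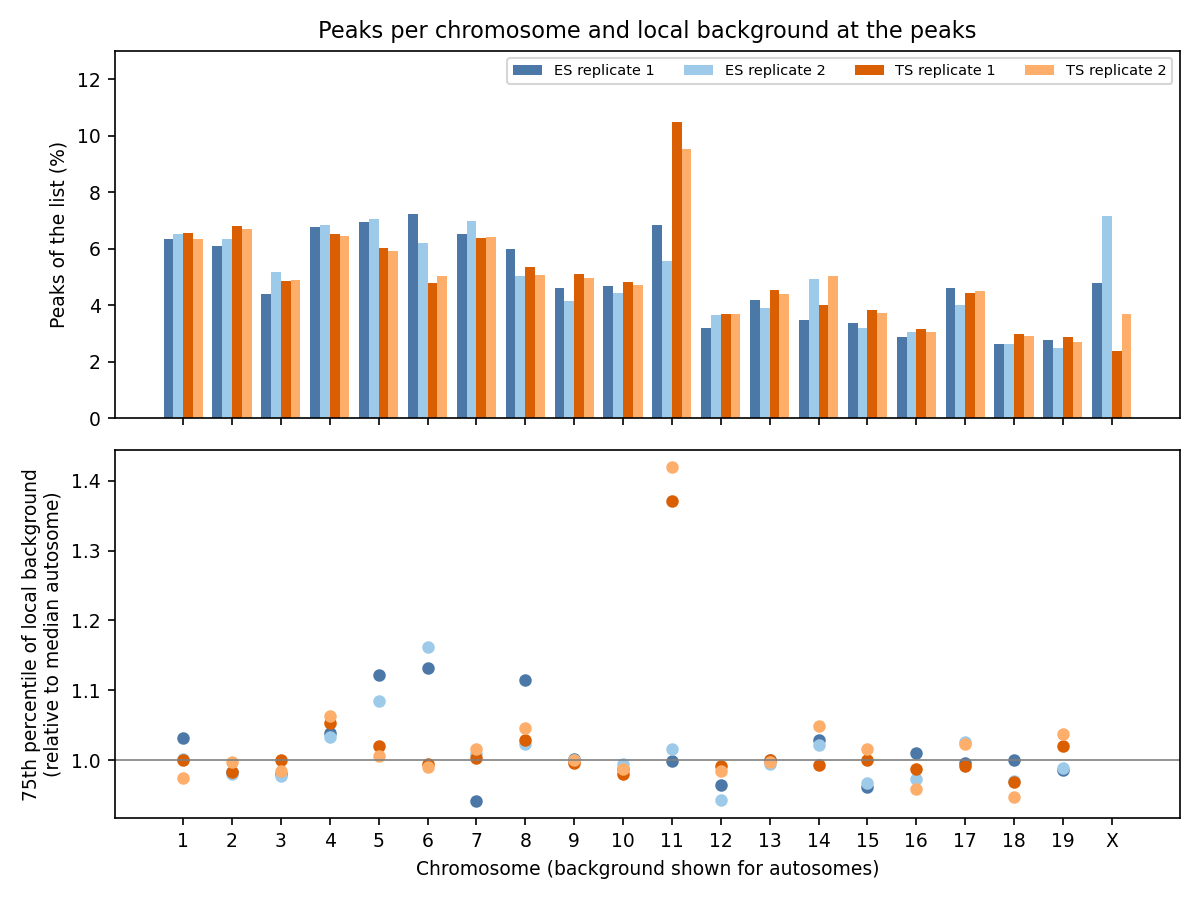
Upper panel, percentage of each list's peaks (vertical axis) on each chromosome, with 1 bar per sample; lower panel, 75th percentile of the local background at the peaks of each autosome, relative to the median autosome of the same sample (1 point per sample, grey line at 1). Chromosome 11 holds 10.5% and 9.54% of the TS peaks, and its background ratio is 1.37 and 1.42 in the TS samples.

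Chromosome 6 leaned the other way, a comparison also made after the counts had been seen. It held 78 of 776 ES-only regions (10.1%), against 4.54% of TS-only regions and 6.07% of regions called in all 4 samples. Its share of peaks was 7.24% and 6.20% in ES replicates 1 and 2, and 4.80% and 5.03% in TS replicates 1 and 2. The local background at its peaks was 1.13 and 1.16 times the autosomal median in the ES lists, and 0.995 and 0.991 times in the TS lists. The next autosome in the ES lists, chromosome 5, was close, at 1.12 and 1.09. At the 90th percentile in place of the 75th, chromosome 6 no longer had the highest background in the ES lists (1.12 and 1.18, against highest values of 2.16 and 1.48).

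Chromosome X took a smaller share of TS than of ES peaks. It held 4.79% and 7.16% of peaks in ES replicates 1 and 2, and 2.37% and 3.68% in TS replicates 1 and 2. The mean number of X peaks was nevertheless 1042.5 in TS and 875.5 in ES lists. The ratio of mean shares was 0.506 (two-sided exact permutation test, p = 0.333, the smallest possible). X held 12.5% and 12.7% of regions shared only by the pairs numbered 1 and 2, but 1.16% of ES-only regions and 4.26% of regions in all 4 samples. Many X peaks thus went by replicate number, and the Fisher p-values below cover counting error only. The odds ratio of X against autosomal peaks, TS against ES, was 0.476 (95% interval 0.427 to 0.531) within replicate number 1 and 0.493 (0.454 to 0.534) within number 2 (Fisher's exact test, p = 1.58e-38 and 2.63e-63). Between the region classes, 180 TS-only regions (1.25%) and 9 ES-only regions (1.16%) lay on X, an odds ratio of 1.07 (0.548 to 2.11; Fisher's exact test, p = 1). That interval is wide with 9 regions, and the ratio depended on the lists. It was 0.130 with lists of equal length and 0.109 with peaks above the median P score. Within replicate numbers 1 and 2 alone, with 1 sample per cell type, it was 0.392 and 0.292. Leaving out each sample gave 0.164 to 0.635. The median pileup of X peaks was 67 and 44 tags in ES replicates 1 and 2, against 25 and 33 over all peaks of those lists, and 46 and 40 tags in TS replicates 1 and 2, against 37 and 36. The local background at X peaks was raised as well, to 3.13 and 2.00 times the autosomal median in the ES lists and 1.82 and 1.19 times in the TS lists. On chromosome Y, 80 regions were called in all 4 samples, 1 was ES-only and 2 were TS-only. The local background at Y peaks was higher than at X peaks. It was 7.45 and 13.8 times the autosomal median in ES replicates 1 and 2, and 10.9 and 8.46 times in TS replicates 1 and 2. Whether the Y regions mark open chromatin or repeated sequence was not tested.

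Of 1172 tested 1 Mb windows, 3 held a mix of ES-only and TS-only regions that differed from the rest of the genome past an adjusted p of 0.05. Chromosome 4 at 146 to 147 Mb held 6 ES-only and 6 TS-only regions (Fisher's exact test, adjusted p = 0.0128), chromosome 10 at 6 to 7 Mb held 6 and 7 (adjusted p = 0.0128), and chromosome 6 at 140 to 141 Mb held 6 and 8 (adjusted p = 0.0142). All were ES-rich, which the test fixed in advance: ES-only regions were 5.10% of both classes, so a window without any needed at least 66 TS-only regions for an unadjusted p below 0.05, and the densest held 46. With all 4 samples, windows rich in TS-only regions could therefore not be found; without ES replicate 1, 32 of 108 windows past the threshold were TS-rich, and without ES replicate 2, 4 of 39. None of the 3 windows was past the threshold with lists of equal length, which gave 6 other windows, or above the median P score, which gave 1 other.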

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

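The tests of extra chromosome 11 copies, of 10 Mb bins, of peaks near the threshold, of both mixtures, of wide repeat arrays, of tag number and of peaks without chromosome 11 were chosen or settled only after the result, or counts that largely fix it, had been seen.

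The local background was reconstructed from the P scores and folds, which both contain it, so it is not independent of the peak comparisons. On chromosome 11 it was raised to 1.37 times the autosomal median in TS replicate 1 and 1.42 times in TS replicate 2, with 0.999 and 1.02 in the ES samples. A few raised regions would leave most of the chromosome near 1, but 13 of 13 bins of 10 Mb (1.19 to 1.55) lay above the 95th percentile of the other autosomes' bins (1.11 and 1.15) in both TS lists. Denser open chromatin would raise the background through neighbouring peaks. The 189 and 199 chromosome 11 peaks with no other peak within 50 kb still had ratios of 1.32 and 1.33, above the highest other autosome (1.03). That argues against called neighbours as the source. Open chromatin near these peaks that was too weak to be called was not covered. The pileup and background of chromosome 11 were also divided by its ratio, among peaks above the median P score. This lowered its TS over ES share ratio from 1.91 to 1.22 (others 0.808 to 1.27). With ratios taken at the median and the 90th percentile it was 1.25 and 1.16 (others up to 1.27 in both). Such a division lowers P scores whatever raised the background, so the fall does not favour extra copies over another source. It shows only that a raised background of this size could account for the larger share. Extra copies of chromosome 11 in some or all of the TS cells would raise the background along the whole chromosome, and remain a hypothesis. A gain in this line was not separated from a property of TS cells, since a single line was sampled.

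The second pattern is the sharing of regions between samples of the same number. The tests of the threshold, of both mixtures and of wide repeat arrays were run on the pair numbered 2 only. The 3572 regions of ES replicate 2 and TS replicate 2 had median P percentiles of 74.0 and 70.2, which argue against peaks near the threshold for that pair. For the 1012 regions of the pair numbered 1, the median P percentiles were 76.5 in ES replicate 1 and 57.6 in TS replicate 1. Strong TS replicate 2 peaks absent from ES replicate 1 were called in ES replicate 2 at 83.1% where TS replicate 1 lacked them (1885 peaks) and at 22.1% where it had them (3222 peaks), a ratio of 3.77 (2.53 to 3.97 within bands of P percentile) that argues against TS replicate 2 material in ES replicate 2 as the whole cause. The reverse mixture cannot be told apart (rates of 69.2% and 50%, a ratio of 1.38, with only 48 peaks in the second group). Wide repeat arrays would raise the local background, but 68.0% of the peaks of the 3572 regions in TS replicate 2 sat at the genome-wide background, against 36.1% of all its peaks. In ES replicate 2 the contrast was smaller, 68.1% against 56.5%. A shared preparation or sequencing batch, short repeats and base composition stay open, since the labels name no batch and no mm9 sequence was used here, and no biological explanation was tested.

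The third pattern is the larger number of TS peaks. More tags alone do not account for it: TS replicate 2, with 39.8 M tags, had 2.13 times the peaks of ES replicate 2, with 42.1 M. Extra chromosome 11 peaks do not account for it either, since the ratio without that chromosome was 2.31. A difference between the cell types and a difference in FAIRE enrichment between preparations stay open and were not tested.

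The local background of chromosome 6 was the highest of the autosomes in the ES samples, at 1.13 in replicate 1 and 1.16 in replicate 2, but not at the 90th percentile of background.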

How the results depend on the processing

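The settings of replicate number 1 or 2 alone, without chromosome 11 and all those of the chromosome 11 share were chosen after seeing the data. Of 78 alternatives, 50 kept a result on its side, 20 moved it and 8 turned it. All 8 turns were of the X odds ratio of regions, which at 1.07 (0.548 to 2.11) had no clear side. The difference in overlap within and between cell types, 15.0 percentage points, counted as kept even at 1.95. Its spread (SD 15.9) was larger than the difference, so that label says little. The overlap rule, joining peaks within 500 bp, autosomes only and leaving out chromosome 11 moved no result they were run on by more than 1.5 times or more than the spread. Limits: leaving out a sample relaxes the demand for 2 replicates, so those counts rise by construction, and equal lists hold fewer peaks. With lists of equal length the ratio of peak numbers was 1 by construction, TS-only regions numbered 2923, regions in all 4 samples 2882 and windows past the threshold 6. Above the median P score, ES-only regions numbered 164, TS-only regions 6632, regions in all 4 samples 1853 and windows 1. Replicate number 1 alone gave 4500 ES-only and 26302 TS-only regions, and number 2 alone 6066 and 24608, where 1 sample per cell type defined the class. Leaving out each sample gave 911 to 5397 ES-only regions, 15868 to 24099 TS-only regions, and 4 to 108 windows. The counts that moved by over 1.5 times were 5397 and 4127 ES-only regions without ES replicates 1 and 2, 22968 and 24099 TS-only regions without TS replicates 1 and 2, and 108, 39 and 12 windows without ES replicate 1, ES replicate 2 and TS replicate 1, of which 1, 2 and 3 were among the original 3. Windows of 500 kb gave 1. The X odds ratio of TS-only against ES-only regions, 1.07, turned to 0.130 with equal lists, 0.109 above the median P score, 0.392 and 0.292 within replicate numbers 1 and 2, and 0.164 to 0.635 leaving out each sample; the cause was not tested. With replicate number as a block (replicate block), the X odds ratio of peaks was 0.487, against 0.473 without it; the number is a label only, and its 2 pairs are too few to show that it pairs the samples. The mean strength probability was 0.755 by P score. The difference in overlap within and between cell types ranged from 1.95 to 26.3 percentage points leaving out each sample. Depth was reconstructed, not given, so a region without a peak is only not detected at 39.8 to 54.3 M tags. Promoter, gene list and Tead4 alternatives were not run.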

Other observations

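The windows named below, the joining of regions within 1 kb and the reading of the ES-only test were chosen after the values had been seen. The 1 Mb windows densest in TS-only regions lay mostly on chromosome 11, which held 13 of the top 20. Its window at 97 to 98 Mb held 46 TS-only regions and 1 ES-only region among 106 regions of any class. That at 115 to 116 Mb held 45 and 1 among 98, and that at 116 to 117 Mb held 42 and 0 among 89. Chromosome 11 is also the one with the raised local background in the TS lists described above. Outside chromosome 11, the densest was chromosome 15 at 76 to 77 Mb, with 34 TS-only and 1 ES-only region among 94. Next came chromosome 18 at 38 to 39 Mb, with 30 and 0 among 73, and chromosome 7 at 52 to 53 Mb, with 30 and 1 among 102. The ranking is by count, so it favours windows with many regions of any class. TS-only regions were 26.4% of all merged regions. The median window with any held 5. On chromosome 5, the window at 66 to 67 Mb held 27 TS-only regions among only 43 regions of any class.

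TS-only regions lay near one another. Of 14436, 34.6% had another within 10 kb, against a mean of 25.3% (23.8 to 26.7) in 1000 shuffles of the classes among the regions of each chromosome (one-sided permutation test, p = 0.001, the smallest these shuffles can give). With regions within 1 kb joined, which removes elements split into several peaks, the share was 27.8% against at most 20.6% in the shuffles. That TS-specific open chromatin forms local clusters is only a hypothesis, found on 1 pair of samples. The shuffled regions included those called in a single sample, 47.4% of the total. Regions called in all 4 samples were not put to this test. The shuffles therefore cannot tell clustering particular to TS-only regions from clustering of any class called in several samples. For ES-only regions the share was 3.87%, or 30 of 776, against a mean of 1.77% and a highest of 4.38% in the shuffles (one-sided permutation test, p = 0.006). With joined regions it was 2.27% (one-sided permutation test, p = 0.049). The share lay inside the whole range of shuffles, which had been set beforehand as the bound against clustering. That range widens with the number of shuffles and was too strict a bound for so few regions, so clustering of ES-only regions was left undecided.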
